A study of Mus musculus with 6 samples.

How the data were processed

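Small intestinal organoids from mice aged 4 to 8 weeks, homozygous for a Rosa26 transactivator and a Col1a1 doxycycline-inducible cassette of 4 factors, were left untreated or given 0.1 or 0.5 µg/ml doxycycline for 3 days, with 2 libraries in each group. Per the labels' protocols, poly-A RNA was made into strand-specific MGI libraries and read as 100 bp pairs on an MGI sequencer. The submitters' processing notes name FastQC, Trim Galore, STAR 2.7.3a and RSEM 1.3.3, and the genome builds GRCm39 and mm10 without saying which was used for these tables. The authors deposited RSEM expected counts per gene, which are estimated counts that need not be whole, and a second table of TPM (transcript share scaled to a fixed total), for the same genes and libraries. RSEM divides reads shared by several genes in proportion to its estimates, so members of families with near-identical copies are uncertain, as are overlapping antisense genes, since the strand setting of the counting is not given in the sources used here. The TPM columns deposited by the authors sum to the same total in each library and carry no depth.

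The tables hold 55416 Ensembl gene identifiers, of which 52083 (94.0%) have a symbol in the GENCODE M21 gene table. The unmatched identifiers hold 0.180 to 0.260% of the counts of a library. No coordinates are given because the build of the tables is not settled.

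Expected counts were rounded to whole numbers. Genes were kept by edgeR's filterByExpr at its default settings by group, which left 16975 genes with 99.96% of the counts. Library sizes were scaled by TMM, with factors from 0.964 to 1.04. All 6 libraries entered one edgeR 4.0.16 quasi-likelihood fit in R 4.3.3, with a mean for each group and no covariate, so that the 3 groups shared one estimate of the spread with 3 residual degrees of freedom. Each pair of groups was compared by a two-sided test with Benjamini-Hochberg adjustment at 0.05 and no fold threshold. The standard error of a log2 fold change was taken from the F statistic of the test. With 2 against 2 libraries an exact test of a single value could not go below a p of 0.333, so the p values rest on the spread pooled across genes.

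Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01 and adjusted over the lists of a comparison. The 26 lists, fixed before the data were examined, cover the 4 factors, the pluripotency network, regeneration-associated epithelium, YAP/TAZ targets, the prostaglandin pathway, crypt base stem cells, Wnt targets, Paneth, goblet, enteroendocrine, tuft and absorptive cells, epithelial identity, mesenchymal transition, gastric and squamous epithelium, the cell cycle, p53 targets, the integrated stress response, mitochondrially encoded genes, interferon, inflammation, cholesterol synthesis, and fibroblast, immune and endothelial markers. Of 499 list entries 419 were among the tested genes, and some genes sit in more than one list. Counts of list members higher or lower are out of the tested genes. A member silent in control was tested only if treated libraries expressed it, so these counts leave out members silent throughout. The genes named in the text were chosen by a rule also fixed in advance: the 4 factors; 9 genes by name; for each comparison the 8 highest and 8 lowest log2 fold changes past the test with at least 5 CPM in a group and no overlap between replicates, leaving out symbols of the Gm and Rik series and marked pseudogenes; the 3 largest changes of each called list in the direction of its call; and the member with the smallest p of each other list. A few genes that the rule names are left out of the text. Members spelled out because a count held 5 or fewer of them follow the same rule. Genes named after their values were seen were Ptges, Vim, the markers of other cell types between the doses, and the genes discussed only among the closing observations. A fold against a group with no counts is a bound against 3 counts per library, a floor of 0.0414 to 0.0687 CPM, and with 1 to 3 counts in a group the ratio is given with an exact 95% interval; both cover counting error only.

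The analysis was tested on simulated data drawn from the control means, with 200 genes changed between 0.5 µg/ml and control and 20 more shifted as a list: 58% of genes changed by 0.5 on the log2 scale were recovered, 90% at 1, 98% at 2 and 100% at 3, with 50 genes at each size among 15795 tested, and 5.03% of the 199 calls were of unchanged genes. The list, shifted by 0.4 on the log2 scale, held 16 of the calls, and camera called it and none of 25 unshifted lists. The simulated genes were drawn independently, so this does not test how camera treats lists of correlated genes. Few genes were changed, whereas 67.5% of tested genes were called at 0.5 µg/ml against control in the data, so these shares may not carry over.

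Replicates differed by more than sampling noise: the chi-square of their counts per degree of freedom was 9.35 in control, 8.87 at 0.1 and 8.24 at 0.5 µg/ml. They were still closely alike. Beyond counting noise, edgeR's common estimate of the spread between replicates was 0.0508 of the mean. The Pearson correlation of their log CPM was 0.994 in control, 0.995 at 0.1 and 0.994 at 0.5 µg/ml. Mitochondrially encoded genes took 7.86 ± 0.427% of counts in control, 7.79 ± 0.232% at 0.1 and 7.57 ± 0.544% at 0.5 µg/ml (SD, n = 2). The first principal component of log CPM held 84.6% of the variance and ordered the groups by dose.

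Alternatives fixed in advance were size factors of DESeq2 and upper quartile scaling, no filter beyond 1 count and a filter of 1 CPM in 4 libraries, the Wald test of DESeq2 1.42.0, limma on log2(TPM + 1) and log2(TPM + 0.1) for genes of at least 1 TPM in 2 libraries, a fit of only the 4 libraries compared, the replicate number as a block, a 2-fold threshold, each library left out in turn, and for lists an estimated correlation and fry. Thinning all libraries to one depth was added after the library totals were seen. No column of the tables was left out.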

Results

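Gene expression was measured by RNA-seq in small intestinal organoids, epithelial cultures grown in a gel from the intestinal lining of mice. The mice carry a transgene that expresses Oct4 (gene Pou5f1), Sox2, Klf4 and Myc from a doxycycline-responsive promoter placed at the Col1a1 locus, together with the reverse tetracycline transactivator at Rosa26. Organoids without doxycycline formed the control group, and the other groups received 0.1 or 0.5 µg/ml doxycycline for 3 days. Each of the 3 groups held 2 libraries, which the series describes as biological replicates. The sources used here do not say whether these are separate mice, organoid lines or cultures, so calls may not carry over to other animals. In units of 1e+06 expected counts, the library totals were 48.3 and 48.4 in control, 72.5 and 48.6 at 0.1 µg/ml, and 45.3 and 53.8 at 0.5 µg/ml. The series describes the doses as a way to induce the factors to different degrees, so the comparisons ask how each dose differed from control and how the doses differed from each other. Levels are given as CPM, counts scaled to a common library size by TMM factors and expressed per 1e+06, with the SD over the 2 libraries of a group.

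All 4 factor genes rose with dose. Pou5f1 (ENSMUSG00000024406) stood at 0.191 ± 0.0732 CPM in control, 139 ± 4.10 CPM at 0.1 µg/ml and 499 ± 18.5 CPM at 0.5 µg/ml (SD, n = 2). Sox2 (ENSMUSG00000074637) stood at 0.210 ± 0.154, 84.8 ± 2.15 and 309 ± 22.3 CPM in the same order. Klf4 (ENSMUSG00000003032) and Myc (ENSMUSG00000022346), which the control epithelium already expressed, went from 30.6 ± 3.32 to 224 ± 0.141 and 759 ± 18.1 CPM, and from 44.4 ± 0.841 to 249 ± 13.1 and 834 ± 61.6 CPM. The rise over control at 0.5 µg/ml was 2579.8-fold for Pou5f1, 1449.7-fold for Sox2, 24.8-fold for Klf4 and 18.8-fold for Myc, with edgeR adjusted p values from 3.16e-12 to 4.33e-11. At 0.1 µg/ml the rise was 716, 397, 7.31 and 5.62-fold in that order, and between the doses the 4 genes rose by 3.35 to 3.65-fold. As a list the factors passed camera at 0.5 µg/ml (adjusted p = 6.61e-35, adjusted p = 0.141 with an estimated correlation), at 0.1 µg/ml (3.95e-83, adjusted p = 0.0310 with an estimated correlation) and between the doses (1.34e-13, adjusted p = 0.208 with an estimated correlation). Gene counts cannot separate transgene reads from reads of the endogenous genes.

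**Figure D1:**
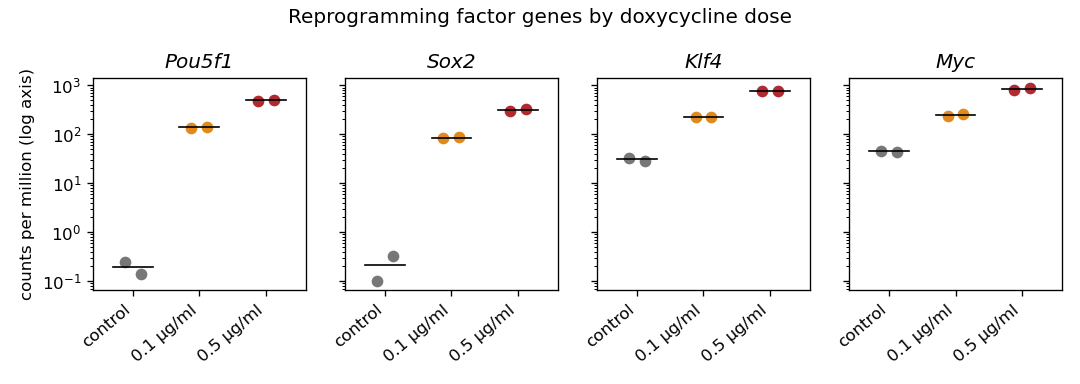
CPM of the 4 factor genes on a log axis, 1 point per library and a line at each group mean, for control, 0.1 and 0.5 µg/ml doxycycline. In each panel the 2 libraries at 0.5 µg/ml lie above those at 0.1 µg/ml, which lie above the control libraries.

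At 0.5 µg/ml 7 of 8 gastric, 12 of 14 squamous and 8 of 17 prostaglandin pathway genes were higher, and 15 of 17 stem, 14 of 16 Paneth, 14 of 17 goblet and 25 of 26 enteroendocrine genes were lower. These lists passed camera at a preset correlation and not with an estimated one (adjusted p = 0.174 to 0.344). Of all 16975 tested genes, 5839 were higher and 5626 lower, and the prostaglandin share stood nearest to that of all genes. Ptgs1 (ENSMUSG00000047250), which encodes cyclooxygenase 1, rose 867-fold from 0.272 ± 0.0740 to 237 ± 16.3 CPM, and Ptgs2 (ENSMUSG00000032487), which encodes cyclooxygenase 2, rose 36.1-fold to 103 ± 5.06 CPM (SD, n = 2). Ly6a (Sca-1) and Anxa1, genes of regenerating intestinal epithelium, rose 6.32-fold and 7.97-fold to 163 ± 1.26 and 213 ± 5.18 CPM. Clu, a marker of the regenerative revival stem cell, moved the other way and fell 2.74-fold, from 74.7 ± 4.26 to 27.2 ± 2.74 CPM. The crypt base stem cell gene Lgr5 fell 13.2-fold from 141 ± 11.9 to 10.6 ± 2.27 CPM, and Olfm4 fell 17.4-fold from 178 ± 87.5 to 10.2 ± 1.15 CPM.

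Of 16975 genes tested, 5839 were higher and 5626 were lower at 0.5 µg/ml than in control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05, two-sided). At least 2-fold changes were seen for 2513 higher and 2086 lower genes. The 8 highest fitted log2 fold changes among genes of at least 5 CPM were of genes with no count in either control library, so their folds are lower bounds against a floor of 3 counts per library. Their fitted rank does not show a larger rise than that of Pou5f1 or Krt13, whose folds exceed these bounds. Prss35, a protease-like protein, reached 109 ± 17.7 CPM, at least 1812-fold higher. Stmn2, a neuronal microtubule regulator, reached 48.7 ± 1.14 CPM, at least 807-fold higher, and Kcnj12, a potassium channel, 39.9 ± 2.40 CPM, at least 662-fold higher. The bounds were 506-fold for the organic anion transporter Slco1a5, 419-fold for Rasgrp1, 393-fold for Myo18b, 305-fold for the meiotic helicase Hfm1 and 231-fold for Ifi209. The 8 lowest were Fras1 (30.7-fold lower), Bmp3 (24.3-fold), the serotonin synthesis enzyme Tph1 (24.0-fold), Tac1 (21.5-fold), Nrp1 (19.5-fold), the glucagon gene Gcg (18.5-fold), Olfm4 and the secretory granule gene Chgb (17.4-fold).

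Among the lists fixed in advance, 8 of 26, that of the factors included, were higher at 0.5 µg/ml. The tested genes were 8 of 15 fixed gastric, 14 of 17 squamous, 15 of 28 pluripotency and 12 of 21 tuft members, the rest being too low to test or not found. Of 8 gastric genes tested, 7 rose, 1 fell and 0 did not pass (camera adjusted p = 2.02e-09, adjusted p = 0.174 with an estimated correlation; median log2 fold change 7.56, or 6.36 with Gkn2, absent from control, at its bound). Muc5ac, the gastric surface mucin, went from 2 counts in control to 90.4 ± 14.1 CPM, a ratio of 4453 with a 95% exact counting interval of 1232 to 36779. Tff1 rose 272-fold, while Vsig1 fell by 1.54 on the log2 scale. Of 14 squamous genes, 12 rose, 1 fell and 1 did not pass (camera adjusted p = 2.39e-09, adjusted p = 0.174 with an estimated correlation; median log2 fold change 4.42, or 3.77 with the 2 genes absent from control at their bounds). The keratins Krt13 and Krt16 rose 4841-fold and 581-fold, Krt17 was at least 28.9-fold higher, and Krt4 fell by 3.49 on the log2 scale. Of 15 pluripotency genes other than the factors, 11 rose, 1 fell and 3 did not pass, the faller being Dnmt3b (camera adjusted p = 1.02e-05, adjusted p = 0.174 with an estimated correlation; median log2 fold change 2.87). Tdh, an enzyme of mouse embryonic stem cells, was at least 217-fold higher, at 13.1 ± 0.282 CPM. L1td1 and Esrrb held 2 and 1 counts over both control libraries and reached 61.3 ± 8.47 and 10.3 ± 1.66 CPM, ratios of 3077 (95% exact interval 851 to 25414) and 1013 (95% exact interval 181 to 40046). Nanog did not pass the low-count filter, with 0 counts in 5 of the 6 libraries and 1 count in 1 library at 0.5 µg/ml.

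Of 26 regeneration-associated genes, 16 rose, 5 fell and 5 did not pass (camera adjusted p = 1.17e-09, adjusted p = 0.174 with an estimated correlation; median log2 fold change 0.81). Tm4sf1 and Anxa8 rose 68.7-fold and 42.5-fold, and the 5 that fell were Clu, F3, Areg, Ereg and Tnfrsf12a. Of 17 prostaglandin pathway genes, 8 rose, 3 fell and 6 did not pass (camera adjusted p = 2.32e-04, adjusted p = 0.174 with an estimated correlation; median log2 fold change 0.55). The prostaglandin transporter Slco2a1 rose 21.6-fold to 96.5 ± 3.87 CPM, and the 3 that fell were Hpgd, Cbr1 and Ptgr1, which act in prostaglandin breakdown or reduction. The PGE2 synthase gene Ptges had a log2 fold change of 0.13 and did not pass the test. Of 20 YAP/TAZ targets, 11 rose, 6 fell and 3 did not pass (camera adjusted p = 5.68e-04, adjusted p = 0.244 with an estimated correlation; median log2 fold change 0.58). Nt5e (CD73) was up 374-fold, Ccn2 up 18.1-fold and Ptpn14 up 6.63-fold. Of 12 tuft cell genes, 7 rose, 2 fell and 3 did not pass (camera adjusted p = 1.03e-08, adjusted p = 0.174 with an estimated correlation; median log2 fold change 2.12). Avil rose 305-fold to 399.6 ± 6.90 CPM and Vav1 rose 206-fold, whereas Trpm5, the taste-transduction channel of tuft cells, fell from 1.05 ± 0.145 to 0.182 ± 0.0953 CPM. Ptgs1 counts in both the tuft and the prostaglandin list.

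The 5 lists lower at 0.5 µg/ml were those of enteroendocrine, Paneth, goblet, crypt base stem and absorptive cells. Of 26 enteroendocrine genes, 1 rose, 25 fell and 0 did not pass (camera adjusted p = 2.69e-11, adjusted p = 0.200 with an estimated correlation; median log2 fold change -3.14), the riser being Pcsk1n. Of 16 Paneth cell genes, 1 rose, 14 fell and 1 did not pass (camera adjusted p = 5.40e-08, adjusted p = 0.174 with an estimated correlation; median -2.57). The defensins Defa24 and Defa17 fell 9.76-fold and 9.64-fold and AY761184 fell 22.0-fold. The riser was Nupr1, and near-identical defensin copies share reads. Of 17 goblet cell genes, 2 rose, 14 fell and 1 did not pass (camera adjusted p = 5.40e-08, adjusted p = 0.174 with an estimated correlation; median -2.14). The mucin gene Muc2 was down 7.10-fold, Spink4 down 8.64-fold and Ccl9 down 13.8-fold, and Clca1 and Galnt12 were higher. Of 17 crypt base stem cell genes, 2 rose, 15 fell and 0 did not pass (camera adjusted p = 1.03e-05, adjusted p = 0.344 with an estimated correlation; median -1.99). Gkn3 fell 11.6-fold, and the risers were Cd44 and Ascl2. Of 29 absorptive enterocyte genes, 1 rose, 19 fell and 9 did not pass (camera adjusted p = 7.87e-05, adjusted p = 0.616 with an estimated correlation; median -0.62). The genes of the brush border peptidases Anpep and Dpp4 were down 4.84-fold and 4.20-fold, the sterol exporter Abcg8 down 2.99-fold, and the peptide transporter Slc15a1 up by 2.43 on the log2 scale. Adjusted over the list alone, 8 gastric, 13 squamous, 12 pluripotency, 21 regeneration, 11 prostaglandin, 17 YAP/TAZ, 10 tuft, 26 enteroendocrine, 15 Paneth, 16 goblet, 17 stem cell and 20 enterocyte genes changed.

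The other 13 fixed lists were not called at 0.5 µg/ml against control, although single members changed. Cdx2, the intestinal master regulator in the epithelial identity list (camera adjusted p = 0.391), fell 3.03-fold, from 178 ± 1.58 to 58.6 ± 2.004 CPM. Fibronectin, Fn1, in the mesenchymal list (adjusted p = 0.205), rose 180.1-fold to 221 ± 25.5 CPM. Cd44 rose 2.21-fold among Wnt targets (adjusted p = 0.361), Tigar 4.59-fold among p53 targets (adjusted p = 0.156), and Psat1 2.03-fold in the integrated stress response list (adjusted p = 0.475). Bst2 rose 4.50-fold in the interferon list (adjusted p = 0.583) and Nos2, the inducible nitric oxide synthase, 41.2-fold in the inflammation list (adjusted p = 0.0649). Ccnb2 fell 1.76-fold among cell cycle genes (adjusted p = 0.144). Higher and lower members numbered 3 and 5 of 11 Wnt, 11 and 11 of 22 identity, 3 and 6 of 11 mesenchymal, 3 and 13 of 28 cell cycle, 11 and 6 of 23 p53, 6 and 7 of 19 stress response, 2 and 2 of 13 mitochondrially encoded, 5 and 11 of 19 interferon, 8 and 5 of 17 inflammation and 7 and 10 of 22 cholesterol genes. The cholesterol list had an adjusted p of 0.156. The mitochondrially encoded list (adjusted p = 0.787) had mt-Atp6 1.31-fold higher, a call lost with limma on log2(TPM + 1) (adjusted p = 0.0587) and without the first library at 0.5 µg/ml (adjusted p = 0.0623). The median and mean log2 fold change had opposite signs in the identity list (-0.05 and 0.18) and in the integrated stress response list (0.06 and -0.10), and in the mitochondrially encoded list both were above 0 while the test pointed down. The p53 list was called without the first control library (adjusted p = 0.0298), and so was the inflammation list (0.0332), which was also called without the first library at 0.5 µg/ml (0.0405). The cell cycle list was called with every gene of at least 1 count (0.00906). With fry, which does not compare a list with other genes, the identity, mesenchymal, cell cycle and cholesterol lists were lower (adjusted p = 0.0119, 3.38e-04, 0.0265 and 0.0119) and the p53 and inflammation lists higher (0.00540 and 0.00161). The senescence gene Cdkn2a did not pass the low-count filter, with 5 to 10 counts per library.

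Markers of cells other than epithelium were low. The fibroblast, immune and endothelial lists were not called (camera adjusted p = 0.475, 0.479 and 0.584), with 4 of 13, 5 of 14 and 4 of 8 members past the low-count filter. With fry all 3 were called higher (adjusted p = 0.00430, 0.00217 and 2.68e-04). Higher and lower members numbered 2 and 1 of 4 fibroblast, 3 and 1 of 5 immune and 3 and 1 of 4 endothelial genes. Col1a1, whose locus carries the transgene, rose from 0.381 ± 0.110 to 3.92 ± 0.203 CPM, Cd68 from 2.23 ± 0.366 to 13.5 ± 0.372 CPM and Tek from 0.171 ± 0.101 to 3.63 ± 0.543 CPM, while Vim fell from 4.92 ± 1.17 to 0.287 ± 0.0822 CPM. None of the 13 list calls at 0.5 µg/ml held when the correlation between genes of a list was estimated from the data. That includes the list of the induced factors (camera adjusted p = 0.141). With an estimate the test also has only 3 residual degrees of freedom, so a lost call does not show that a list was unchanged. With limma on log2(TPM + 1), over fewer genes, 3816 genes were higher and 5085 lower at 0.5 µg/ml, so that 42.9% of the calls were higher against 50.9% with edgeR. Upper quartile scaling gave 5121 higher and 6592 lower (43.7%).

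**Figure D2:**
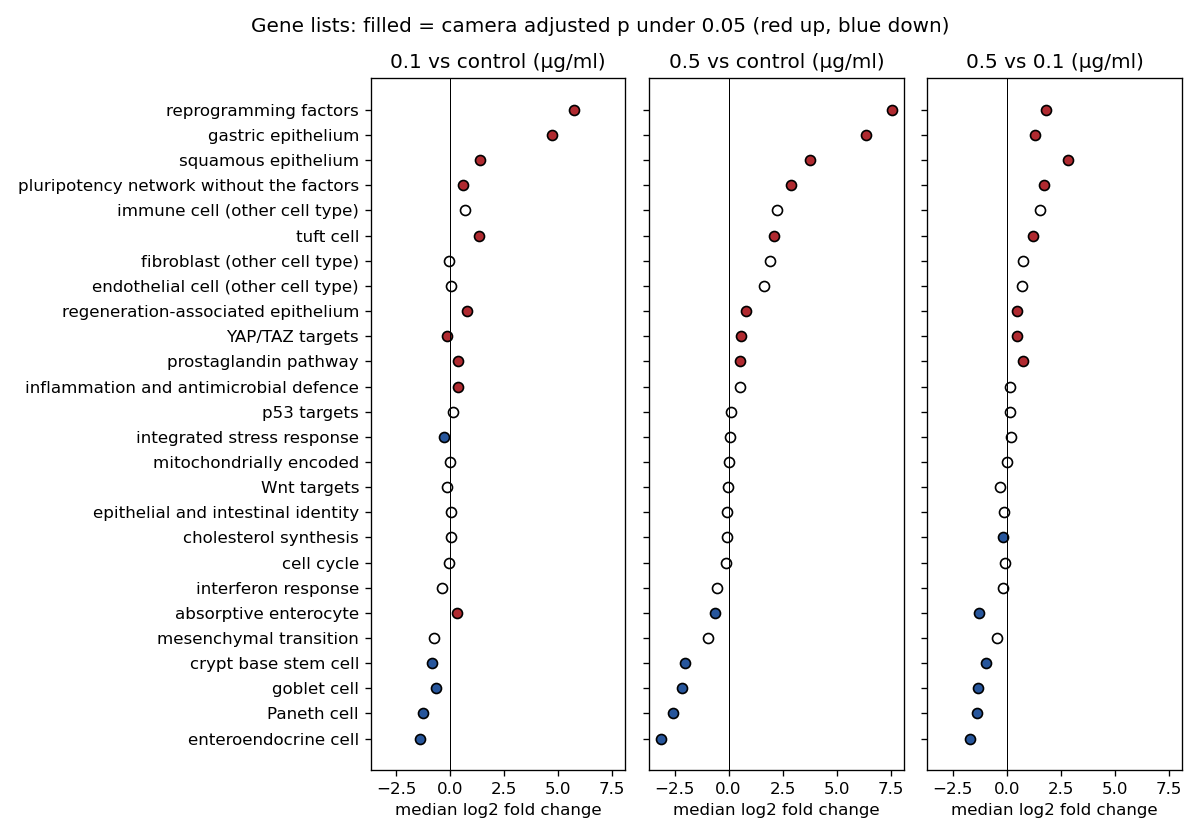
Median log2 fold change of each fixed list, with genes absent from a group at their bound, for the 3 comparisons. Filled points passed camera with a preset correlation (red higher, blue lower) and open points did not. The enterocyte list lies at 0.33 at 0.1 µg/ml and at -0.62 at 0.5 µg/ml.

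At 0.1 µg/ml 7 of 8 gastric, 8 of 14 squamous and 16 of 26 regeneration genes were higher, and 15 of 17 stem, 15 of 16 Paneth, 12 of 17 goblet and 24 of 26 enteroendocrine genes were lower. These lists passed camera at a preset correlation and not with an estimated one (adjusted p = 0.130 to 0.276). Ptgs1 rose 160.5-fold to 43.9 ± 3.01 CPM, Ptgs2 7.10-fold to 20.2 ± 0.601 CPM, Ly6a 2.79-fold to 71.8 ± 4.27 CPM and Anxa1 2.56-fold to 68.3 ± 3.04 CPM. Lgr5 fell 3.17-fold to 44.8 ± 16.1 CPM and Olfm4 4.92-fold to 36.7 ± 20.5 CPM. Clu stood at 64.0 ± 11.9 CPM against 74.7 ± 4.26 CPM in control and did not pass the test (edgeR adjusted p = 0.156); without the first library at 0.1 µg/ml (adjusted p = 0.00669) and with every gene of at least 1 count (adjusted p = 3.82e-04) it did, while the other alternatives gave up to 0.607. Without that library its log2 fold change was -0.44.

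The test called 3531 genes higher and 2350 lower at 0.1 µg/ml, so that 60.0% of the calls were higher. Upper quartile scaling gave 3037 higher and 2986 lower (50.4%). The 8 highest fitted log2 fold changes were those of Prss35 (at least 119.7-fold), Hfm1 (at least 103-fold), Rasgrp1 (at least 87.9-fold), Cd109, Muc5ac, Pou5f1, Aldh3a1 and Sema5b. For the genes given as bounds the rank does not show a larger rise than that of the rest. Cd109 and Muc5ac held 2 counts each over the control libraries and reached 30.9 ± 3.69 and 19.5 ± 0.640 CPM, ratios of 1565 (95% exact interval 433 to 12925) and 976 (95% exact interval 269.9 to 8065). Aldh3a1 and Sema5b, with 3 counts and 1 count in control, reached 21.7 ± 0.285 and 6.82 ± 0.817 CPM, ratios of 722 (247 to 3503) and 689 (123 to 27256). The 8 lowest were the incretin gene Gip (5.85-fold lower), Olfm4, Tac1 (4.50-fold), somatostatin, Sst (4.25-fold), Bmp3 (4.24-fold), Nrp1 (4.21-fold), Slc16a12 (3.93-fold) and Ccl9 (3.90-fold).

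Of the gastric genes 7 rose, 0 fell and 1 did not pass (median 6.17, or 4.72 with Gkn2 at its bound, camera adjusted p = 1.72e-22, adjusted p = 0.130 with an estimated correlation). Tff1 was up 109-fold to 18.8 ± 1.76 CPM and Gkn2 at least 10.9-fold higher. Of the squamous genes 8 rose, 1 fell and 5 did not pass (median 1.70, or 1.38 with 2 genes at their bounds, adjusted p = 1.35e-07, adjusted p = 0.149 with an estimated correlation). Krt13 was up 547-fold, Krt16 up 38.2-fold and Krt6a up 30.2-fold, and Krt4 was lower. Of the pluripotency genes 9 rose, 1 fell and 5 did not pass (adjusted p = 4.64e-07, adjusted p = 0.149 with an estimated correlation); their median was 2.12, or 0.59 with the 2 genes absent from control at their bounds. Tdh was at least 25.8-fold higher, and L1td1 and Esrrb reached 10.6 ± 0.367 and 5.63 ± 0.488 CPM, and Dnmt3b fell. Of the regeneration genes 16 rose, 4 fell and 6 did not pass (adjusted p = 4.91e-11, adjusted p = 0.176 with an estimated correlation). Tm4sf1 was up 11.2-fold and Anxa8 up 10.3-fold, and Areg, F3, Krt7 and Tnfrsf12a were lower. Of the prostaglandin genes 9 rose, 1 fell and 7 did not pass (adjusted p = 3.17e-06, adjusted p = 0.130 with an estimated correlation). Slco2a1 was up 6.44-fold and the phospholipase gene Pla2g4a was lower; Hpgd and Ptgr1, lower at 0.5 µg/ml, were higher here. Of the tuft cell genes 8 rose, 1 fell and 3 did not pass (adjusted p = 7.27e-17, adjusted p = 0.130 with an estimated correlation). Avil was up 108-fold to 141 ± 0.443 CPM, Vav1 up 34.9-fold and Trpm5 at 0.586 ± 0.0497 CPM. Of the inflammation genes 7 rose, 2 fell and 8 did not pass (adjusted p = 0.00255, adjusted p = 0.372 with an estimated correlation). Saa1 was at least 12.3-fold higher, Cxcl5 up 19.2-fold, Nos2 up 14.3-fold, and Reg3b and Reg3g were lower. Of the YAP/TAZ targets 7 rose, 5 fell and 8 did not pass (adjusted p = 0.0144, adjusted p = 0.346 with an estimated correlation); Nt5e rose 76.7-fold, Ccn2 3.27-fold and Ptpn14 2.37-fold, but the list's median was -0.13, opposite in sign to its mean of 0.25 and its test. The YAP/TAZ call was lost without the second control library (adjusted p = 0.189) and with every gene of at least 1 count (0.149), with a range of 0.00683 to 0.346 over all alternatives.

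The absorptive enterocyte list was called higher at 0.1 µg/ml at a preset correlation (camera adjusted p = 0.0302) and not with an estimated one (adjusted p = 0.779). Of its 29 genes 17 rose, 3 fell and 9 did not pass, with a median log2 fold change of 0.33. The peptide transporter Slc15a1 rose 3.93-fold to 9.06 ± 1.08 CPM, the trehalase gene Treh 2.39-fold to 19.7 ± 4.68 CPM and the glucose transporter gene Slc2a2 2.19-fold to 31.8 ± 10.02 CPM, while Anpep, Dpp4 and Ada fell. The list's call was lost without the first library at 0.1 µg/ml (adjusted p = 0.141, median 0.13), without the first control library (0.0790) and with fry (0.117), with a range of 5.66e-07 to 0.779 over all alternatives. The enteroendocrine, Paneth, stem cell and goblet lists were lower (camera adjusted p = 1.54e-16, 3.83e-12, 1.92e-07 and 9.55e-05, against adjusted p = 0.152, 0.149, 0.276 and 0.272 with an estimated correlation). Of the enteroendocrine genes 0 rose, 24 fell and 2 did not pass; of the Paneth genes 0 rose, 15 fell and 1 did not pass. Defa17 was down 3.23-fold, Habp2 3.10-fold and AY761184 7.97-fold. Of the stem cell genes 1 rose, 15 fell and 1 did not pass, with Smoc2 down 2.78-fold and Cd44 higher. Of the goblet genes 2 rose, 12 fell and 3 did not pass, and Spink4 was down 2.59-fold and Creb3l1 2.21-fold, and Clca1 and Zg16 were higher. The integrated stress response list was lower too (2 rose, 10 fell and 7 did not pass; camera adjusted p = 0.00792, adjusted p = 0.346 with an estimated correlation). Atf5 was down 1.54-fold, Trib3 1.44-fold and Vldlr 1.43-fold, and Chac1 and Psat1 were higher. Adjusted over the list alone, 7 gastric, 11 squamous, 10 pluripotency, 20 regeneration, 12 prostaglandin, 9 tuft, 9 inflammation, 15 YAP/TAZ, 20 enterocyte, 26 enteroendocrine, 16 Paneth, 16 stem cell, 14 goblet and 12 stress response genes changed.

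The lists not called at 0.1 µg/ml were Wnt targets, epithelial identity, mesenchymal transition, cell cycle, p53 targets, mitochondrially encoded, interferon, cholesterol, fibroblast, immune and endothelial genes (camera adjusted p = 0.243, 0.500, 0.330, 0.150, 0.330, 0.721, 0.451, 0.745, 0.604, 0.721 and 0.577). Their members with the smallest p included Krt8 (1.60-fold higher), Fn1 (103-fold higher, 127 ± 10.1 CPM), Cd44 (1.35-fold), Tigar (1.81-fold), Mx1 (5.89-fold), Col1a1 (4.18-fold), Cd68 (2.12-fold) and Tek (9.37-fold). The mesenchymal list had a median log2 fold change of -0.77 and a mean of 0.06, and in the cholesterol list both were above 0 (0.04 and 0.02) while the test pointed down. Higher and lower members numbered 2 and 5 of 11 Wnt, 9 and 7 of 22 identity, 3 and 6 of 11 mesenchymal, 0 and 5 of 28 cell cycle, 9 and 3 of 23 p53, 0 and 0 of 13 mitochondrially encoded, 3 and 7 of 19 interferon, 5 and 3 of 22 cholesterol, 1 and 0 of 4 fibroblast, 1 and 0 of 5 immune and 2 and 1 of 4 endothelial genes. With fry the mesenchymal list was lower (adjusted p = 0.0175), and the identity, p53, fibroblast, immune and endothelial lists were higher (0.00931, 0.0473, 0.0411, 0.0360 and 0.00206). Without the first control library the p53 list (adjusted p = 0.0359) and the interferon list (0.0255) were called. The Wnt and cell cycle lists were called without the second library at 0.1 µg/ml (adjusted p = 0.0236 for each) and with every gene of at least 1 count (0.0435 and 0.0255). Of the 15 list calls at 0.1 µg/ml that of the factors alone held with an estimated correlation. The gene counts at 0.1 µg/ml were lower with any 1 of the 6 libraries left out, and lowest without the first library of that group. Thinning all libraries to one depth left 3379 genes higher and 2238 lower, so the greater depth of that library explains little of the counts.

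**Figure D3:**
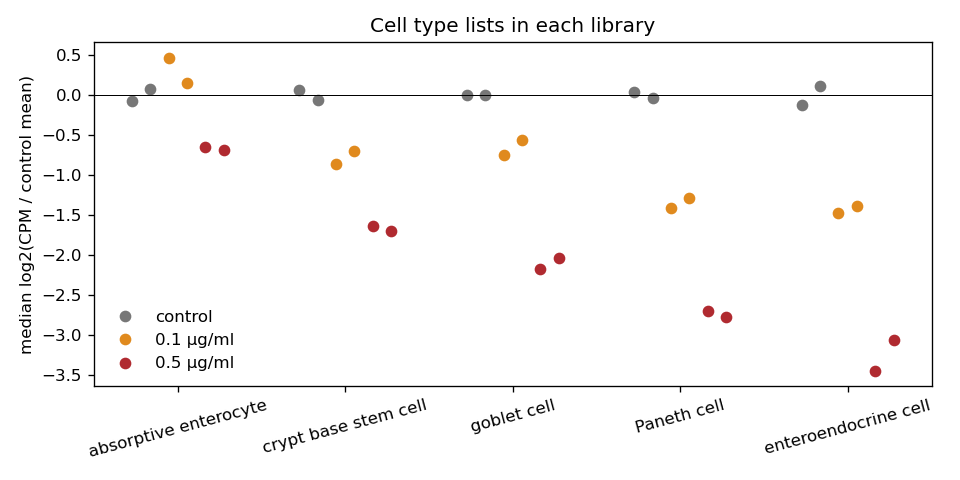
Median over the genes of 5 cell type lists of log2(CPM over the control mean), 1 point per library, for members with at least 1 CPM in control. The enterocyte points are at 0.46 and 0.14 at 0.1 µg/ml and at -0.65 and -0.68 at 0.5 µg/ml; the other 4 lists fall at both doses.

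Between the doses 12 of 14 squamous genes were higher at 0.5 µg/ml, and 26 of 29 enterocyte, 15 of 17 goblet, 22 of 26 enteroendocrine and 12 of 16 Paneth genes were lower. These lists passed camera at a preset correlation and not with an estimated one (adjusted p = 0.208 to 0.362). Cnfn, which encodes cornifelin, rose 35.0-fold from 1.51 ± 0.308 to 52.0 ± 8.07 CPM, and Nlrp10 rose 27.5-fold to 149 ± 16.1 CPM (SD, n = 2). Fabp2, the intestinal fatty acid binding protein, fell 3.30-fold from 260.3 ± 51.3 to 78.8 ± 3.89 CPM, and Dmbt1 fell 5.61-fold from 244 ± 67.3 to 43.7 ± 7.01 CPM. Of the genes fixed by name, Ptgs1 (5.40-fold), Ptgs2 (5.08-fold), Anxa1 (3.12-fold) and Ly6a (2.26-fold) were higher at 0.5 than at 0.1 µg/ml, and Lgr5 (4.15-fold), Olfm4 (3.53-fold) and Clu (2.35-fold) were lower.

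Between the doses 5060 genes were higher and 4942 lower at 0.5 µg/ml, so that 50.6% of the calls were higher. The balance reversed with upper quartile scaling, at 4507 higher and 5587 lower (44.7%), and with limma on log2(TPM + 1), at 3146 and 4268 (42.4%). The 8 highest fitted log2 fold changes were those of the clone-named gene AC151284.2 (90.3-fold), Myo18b (53.7-fold), Vsig8 (39.1-fold), Spink2 (38.8-fold), Cnfn, Ttc28 (28.0-fold), Nlrp10 and AC151284.1 (26.8-fold). The 8 lowest were Bmp3 (5.74-fold lower), Dmbt1, Gcg (5.60-fold), Chgb (5.19-fold), transthyretin, Ttr (4.79-fold), cholecystokinin, Cck (4.78-fold), Cyp2c38 (4.58-fold) and Ugt1a9 (4.52-fold). Cyp2c38 and Ugt1a9 belong to families of near-identical genes that share reads.

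Of the 29 enterocyte genes 2 rose, 26 fell and 1 did not pass between the doses (camera adjusted p = 1.34e-13, adjusted p = 0.362 with an estimated correlation; median log2 fold change -1.30). Enpep was down 3.18-fold and the lactase gene Lct 3.10-fold, and Slc15a1 and Ada were higher. Of the squamous genes 12 rose, 1 fell and 1 did not pass (adjusted p = 6.54e-10, adjusted p = 0.208 with an estimated correlation; median 2.85). Krt17 was up 40.4-fold, Krt16 15.2-fold and Krt6a 13.4-fold, and Krt4 was lower. Of the pluripotency genes 10 rose, 0 fell and 5 did not pass (adjusted p = 3.96e-04, adjusted p = 0.227 with an estimated correlation). Lin28a was up 11.8-fold, Sall4 11.7-fold and Zfp42 9.18-fold, each below 3 CPM at 0.5 µg/ml. The regeneration list (14 rose, 4 fell and 8 did not pass; adjusted p = 3.61e-07, adjusted p = 0.227 with an estimated correlation) and the YAP/TAZ list (12 rose, 4 fell and 4 did not pass; adjusted p = 2.86e-04, adjusted p = 0.227 with an estimated correlation) were higher at 0.5 µg/ml. So were the prostaglandin list (9 rose, 4 fell and 4 did not pass; adjusted p = 0.00411, adjusted p = 0.227 with an estimated correlation), the tuft list (7 rose, 3 fell and 2 did not pass; adjusted p = 1.69e-04, adjusted p = 0.333 with an estimated correlation) and the gastric list (7 rose, 1 fell and 0 did not pass; adjusted p = 0.00242, adjusted p = 0.414 with an estimated correlation). Examples were Sprr1a (4.23-fold), Ccn2 (5.54-fold), Lats2 (3.13-fold), Slco2a1 (3.35-fold), Dclk1 (7.74-fold), Vav1 (5.90-fold), Muc5ac (4.62-fold) and Cldn18 (2.88-fold). Members that fell were Clu, Il33, Areg and F3 of the regeneration list, F3, Crim1, Gadd45a and Nuak2 of the YAP/TAZ list, Ptges2, Hpgd, Ptgr1 and Cbr1 of the prostaglandin list, Trpm5, Ltc4s and Ptpn6 of the tuft list, and Vsig1 of the gastric list. The goblet list (1 rose, 15 fell and 1 did not pass; adjusted p = 6.61e-08, adjusted p = 0.227 with an estimated correlation) and the enteroendocrine list (1 rose, 22 fell and 3 did not pass; adjusted p = 1.78e-06, adjusted p = 0.333 with an estimated correlation) were lower. So were the Paneth list (1 rose, 12 fell and 3 did not pass; adjusted p = 4.04e-04, adjusted p = 0.227 with an estimated correlation) and the stem cell list (2 rose, 13 fell and 2 did not pass; adjusted p = 0.00232, adjusted p = 0.471 with an estimated correlation). Agr2 was down 3.53-fold, Muc2 3.74-fold, Tph1 6.64-fold, Itln1 2.79-fold and Smoc2 3.57-fold. Members that rose were Galnt12 of the goblet list, Pcsk1n of the enteroendocrine list, Nupr1 of the Paneth list, and Ascl2 and Cd44 of the stem cell list. Of the cholesterol synthesis genes 6 rose, 12 fell and 4 did not pass (adjusted p = 0.0413, adjusted p = 0.670 with an estimated correlation; median -0.17). Lss was down 1.55-fold and Acat2 1.53-fold. The cholesterol call was lost with DESeq2 size factors (adjusted p = 0.0648), without the second library at 0.1 µg/ml (0.0891) and without the first at 0.5 µg/ml (0.0779), with a range of 0.00884 to 0.670 over all alternatives.

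The lists not called between the doses were Wnt targets, epithelial identity, mesenchymal transition, cell cycle, p53 targets, integrated stress response, mitochondrially encoded, interferon, inflammation, fibroblast, immune and endothelial genes (camera adjusted p = 0.530, 0.0547, 0.232, 0.232, 0.203, 0.549, 0.862, 0.809, 0.340, 0.458, 0.433 and 0.715). The identity list was called with a replicate block (adjusted p = 0.0494), without the second control library (0.0463), without the second library at 0.1 µg/ml (0.0354) and with fry (0.00243), with a range of 0.00243 to 0.373 over all alternatives. The cell cycle list was called with every gene of at least 1 count (0.0482). With fry the mesenchymal list was lower (adjusted p = 8.41e-04), and the p53, stress response, inflammation, fibroblast, immune and endothelial lists were higher (0.0201, 0.0343, 0.0235, 0.0137, 0.00762 and 0.00167). Higher and lower members numbered 4 and 6 of 11 Wnt, 9 and 11 of 22 identity, 3 and 6 of 11 mesenchymal, 3 and 12 of 28 cell cycle, 11 and 6 of 23 p53, 12 and 6 of 19 stress response, 0 and 0 of 13 mitochondrially encoded, 3 and 7 of 19 interferon, 5 and 6 of 17 inflammation, 2 and 1 of 4 fibroblast, 3 and 1 of 5 immune and 2 and 1 of 4 endothelial genes. Cdx2 fell 2.36-fold and Mmp14 3.03-fold, whereas Bst2 rose 2.90-fold, Cxcl5 7.11-fold and Tigar 2.53-fold. Of the markers of other cell types, Col1a1, Cd68 and Tek rose by 1.29, 1.51 and 1.16 on the log2 scale, and Vim fell by 2.49. The inflammation list had a median log2 fold change of 0.16 and a mean of -0.03. Adjusted over the list alone, 28 enterocyte, 13 squamous, 10 pluripotency, 18 regeneration, 17 YAP/TAZ, 13 prostaglandin, 10 tuft, 8 gastric, 16 goblet, 24 enteroendocrine, 13 Paneth, 15 stem cell and 18 cholesterol genes changed. None of the 14 list calls between the doses held with an estimated correlation, that of the factors included. The tuft call between the doses was also lost with every gene of at least 1 count (adjusted p = 0.0783), with a range of 8.65e-05 to 0.333 over all alternatives.

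Most genes that changed at 0.1 µg/ml changed in the same direction at 0.5 µg/ml. Of the genes higher at 0.1 µg/ml, 2982 (84.5%) were also higher at 0.5 µg/ml, and of those lower, 2118 (90.1%) were also lower. Independent lists of these sizes would share 1215 and 779 genes. The covariance of the log2 fold changes was 1.90 against 0.0870 in 20 simulations of unchanged groups against the same controls. Their correlation was 0.887 against 0.531, and 77.9% of genes had the same sign against 67.0%, so part of the agreement comes from the shared controls. Both comparisons use the same 2 control libraries. With each dose against its own control library, in either assignment and chosen after the overlap was seen, the correlation was 0.818 and 0.785. The genes higher at both doses then numbered 2432 and 2407, and those lower at both 1573 and 1602. Genes passing all 3 comparisons in one direction numbered 2354 rising and 1582 falling with each step of dose.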

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

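The list test, its estimated correlation, the other scalings and the fits without a library were planned, and thinning was chosen before its result was seen. Weighing them as explanations of the patterns was chosen after.

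The absorptive enterocyte list differed between the doses by a direct test: its median log2 difference, 0.5 against 0.1 µg/ml, was -1.30 (camera adjusted p = 1.34e-13, 0.362 with an estimated correlation), and its medians against control were 0.33 at 0.1 and -0.62 at 0.5 µg/ml (adjusted p = 0.779 and 0.616 with an estimated correlation). Of its 29 genes 17 rose at 0.1 µg/ml and 19 fell at 0.5 µg/ml. The choice among the scalings is argued against, since the median at 0.1 µg/ml was at least 0.295 under the others. All of them rest on the measured genes themselves, so an error that they share was not tested. The greater depth of a library at 0.1 µg/ml is also argued against, since the median was 0.33 after thinning to one depth. The rise at 0.1 µg/ml may come in part from its first library: without it the median was 0.13 and the list's call was lost, so with 2 libraries a rise of the group and a chance excess of that library cannot be told apart, while the fall at 0.5 µg/ml kept its call with each library left out in turn but lost it with an estimated correlation. A response to dose stays open and was not tested further, and doxycycline itself was not separated from the factors, since no organoids without the transgene were analysed here.

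By edgeR, 232 genes were called in opposite directions against control at the 2 doses. All of them also passed the gene test between the doses, which adds little, since opposite calls against the same controls nearly imply it. Of the 232 genes 190 were higher at 0.1 and lower at 0.5 µg/ml, 9 of them from the enterocyte list, and 42 were the reverse. With a separate control library for each dose, an alternative chosen after, 119 or 297 genes were called in opposite directions, by assignment.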

How the results depend on the processing

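A separate control library for each dose was added after the overlap was seen and gave overlaps of 4005 and 4009 genes. Thinning to one depth was added after the library totals were seen; its counts and list calls stayed within 1.5 times of those reported. All 12 calls of the 4 factors across the comparisons held under every alternative except the 2-fold threshold, thinning and the separate controls, for which they were not computed. Counts of genes stayed within 1.5 times, higher and lower alike, under both other scalings, both filters, the DESeq2 test, the fit of 4 libraries and the block. With a 2-fold threshold, which by construction calls fewer genes, the counts higher and lower were 2513 and 2086 at 0.5 µg/ml, 1172 and 466 at 0.1 µg/ml and 1801 and 1474 between the doses, and the overlap of the comparisons against control was 1475 genes. On log2(TPM + 1), with 13313 genes tested, they were 3816 higher and 5085 lower at 0.5 µg/ml, 1945 higher and 1560 lower at 0.1 µg/ml, and 3146 higher and 4268 lower between the doses; on log2(TPM + 0.1) 3806 were higher at 0.5 µg/ml, 2024 higher and 1484 lower at 0.1 µg/ml, and 3115 higher between the doses. Part of this is the smaller set of genes and the rest of the cause was not tested. Estimating the correlation within each list left 0 lists higher and 0 lower at 0.5 µg/ml, 1 higher and 0 lower at 0.1 µg/ml, and 0 and 0 between the doses. With an estimate camera also uses the few residual degrees of freedom. The prostaglandin list at 0.5 µg/ml against control had an estimated correlation of -0.0489, below the preset 0.01. A higher correlation of its own genes therefore did not cost it its call. The enterocyte list had 0.695 in that comparison. For the lists together the shares of the causes were not tested. With fry, which does not compare a list with other genes, 13 lists were higher and 9 lower at 0.5 µg/ml, and 14 were higher between the doses.

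Leaving out each library in turn gave 5047 to 5937 genes higher and 5033 to 5870 lower at 0.5 µg/ml, 2352 to 2963 genes higher and 1448 to 2291 lower at 0.1 µg/ml, 4143 to 5413 genes higher and 3976 to 5105 lower between the doses, an overlap of 3490 to 4521 genes, and 8 to 10 lists higher and 5 lower at 0.5 µg/ml, 9 to 10 lists higher and 5 to 7 lower at 0.1 µg/ml, 8 lists higher and 5 to 7 lower between the doses. The lowest counts at 0.1 µg/ml, 2352 and 1448, came without its first library, as did the fewest genes lower at both doses, 1368; the library left alone in a group was taken to vary like the others. The replicate numbers did not pair the samples: the differences between same-numbered libraries correlated at -0.0390, 0.0767 and 0.01003 between groups, and the block gave 5707 genes higher and 5455 lower at 0.5 µg/ml, 3217 genes higher and 2048 lower at 0.1 µg/ml, 4869 genes higher and 4738 lower between the doses. Among values of single named genes under the alternatives, 5 lost and 11 gained a call and none reversed a call; among those of lists 50 lost and 37 gained a call and none reversed one. The values that moved among genes were those of mt-Atp6, mt-Nd6, Clu at 0.1 µg/ml, and Gkn3 between the doses, which lost its call with DESeq2 and without the second library at 0.5 µg/ml. Of the other scalings, upper quartile moved the median log2 fold change of all genes furthest, at 0.5 µg/ml against control from -0.0045 to -0.093. At this depth, genes under the filter such as Nanog and Cdkn2a could not be compared, and changes of 0.5 on the log2 scale were recovered in part in simulation.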

Other observations

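The gene and list tests of this part were planned; the family tests and the weighing of explanations were chosen after the values were seen.

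Gene families defined by the stem of their names were tested for excess among genes at least 2-fold changed at 0.5 µg/ml (one-sided Fisher's exact test, adjusted over 267 families of at least 8 tested genes). Of 24 keratin genes, 16 were at least 2-fold higher, against 14.5% of the background genes (adjusted p = 2.31e-06). All 8 Sprr genes, which encode cornified envelope proteins, were in this set (adjusted p = 1.75e-05), as were 7 of 9 kallikrein genes (adjusted p = 0.00199), 9 of 16 Klf genes (adjusted p = 0.00487) and 8 of 13 synaptotagmin genes (adjusted p = 0.00487). Among genes at least 2-fold lower were 12 of 14 alpha-defensins (adjusted p = 2.24e-07), 14 of 26 Cyp2 genes (adjusted p = 5.31e-05) and 6 of 9 Pcdhb protocadherins (adjusted p = 0.0185). Neighbouring copies share reads and regulation, so members are not independent. The keratin and Sprr genes overlap the squamous list, and the alpha-defensins overlap the Paneth list. The Klf genes at least 2-fold higher include the induced factor Klf4 and Klf2 of the pluripotency list, while Klf1, Klf5 and Klf7 were at least 2-fold lower. The embryonic globin gene Hbb-y, with no count in control, reached 11.4 CPM at 0.5 µg/ml; 27 genes with no count in either control library had at least 5 CPM at 0.5 µg/ml, and 3 at 0.1 µg/ml.

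The genes higher at 0.1 and lower at 0.5 µg/ml included the retinol carrier gene Rbp2 (log2 fold change 0.80 at 0.1 and -0.62 at 0.5 µg/ml), Cyp3a25 (1.01 and -0.58) and Gsta1 (0.70 and -0.35). No family of at least 8 tested genes passed: the smallest adjusted p of the family tests (Fisher's exact test) was 0.0978. Smaller families were left out, and name stems split groups such as Gsta and Gstm. These tests therefore cannot exclude a family shared by these genes.

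The tuft list was called higher at 0.5 µg/ml at a preset correlation (adjusted p = 1.03e-08) and not with an estimated one (0.174), and its members moved apart. A larger share of tuft cells would raise all their markers, but 2 detected members of 12, Trpm5 and Ptpn6, fell at 0.5 µg/ml, which argues against that share as the whole cause. The 7 members that rose carry 7 different name stems, but all 12 tested members differ in stem, so this says nothing about reads shared with related genes, which stays open. The risers also included Pou2f3 and Sh2d6, with log2 fold changes of 2.57 and 6.14 at 0.5 µg/ml. Induction of genes such as Ptgs1, Avil and Vav1 apart from a tuft cell program may account for some of the higher members and was not tested. The markers Il25, Alox5ap and Gnat3 stayed below the low-count filter.

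Single markers of other cell types rose at 0.5 µg/ml, and contamination by such cells was weighed. Fibroblasts are argued against, since Col3a1, Col1a2 and Sparc summed to 0 CPM at 0.5 µg/ml while Dcn stood at 1.78 CPM and Vim fell by 4.07 on the log2 scale. Leukocytes are argued against as the source of Cd68, since Laptm5, Tyrobp, Cd3e and Cd79a summed to 0.482 CPM while Cd68 stood at 13.5 CPM and Itgam fell by 1.34 on the log2 scale. Endothelial cells are argued against as the source of Tek and Esam, since Pecam1, Cdh5 and Emcn summed to 0.165 CPM while Tek stood at 3.63 CPM, Esam rose from 2.84 to 4.51 CPM and Egfl7 fell by 1.16. Ptprc and Coro1a (0.905 CPM together) and Tie1 (0.371 CPM) rose too, at levels too low to decide on a few such cells, and expression within the epithelium stays open as a hypothesis.

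The 4 factor genes rose by different folds, but the CPM they added over control grew from 0.1 to 0.5 µg/ml by 3.60 for Pou5f1, 3.65 for Sox2, 3.78 for Klf4 and 3.85 for Myc. The largest of these factors was 1.07 times the smallest, less than the range between replicate libraries of Myc alone, 3.48 to 4.26. Any co-induced transcripts would share such growth, and the TPM added at 0.5 µg/ml, computed with the lengths of the annotated genes, differed 3.90-fold between the genes. The lengths of the cassette were not used, so that difference does not count against 1 shared transcript. The mice are described as carrying a cassette of the 4 factors under a doxycycline-responsive promoter. Gene counts alone do not decide whether 1 transcript carries all 4, and reads across the cassette could test it.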
